A study of Mus musculus with 6 samples.

How the data were processed

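The study profiled RNA from macrophages sorted by flow cytometry as CD45-positive and F4/80-positive cells from mouse skeletal muscle 3 days after injury with barium chloride, which kills myofibres and starts regeneration. All mice carried a tamoxifen-inducible Cre recombinase under the Cx3cr1 promoter and Manf alleles flanked by recombination sites. Tamoxifen was given to delete Manf, and oil was given to the control mice of that genotype. Total RNA was extracted with the RNeasy Micro Kit, per the labels. There were 3 libraries per group, and their group and number come from the titles and treatment labels. Nothing in the labels says which library came from which mouse, so p-values measure the spread between these samples, which may be technical.

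The values used are FPKM per gene and library, deposited by the authors as 1 table. The unit comes from the name of the deposited table and from its values. The genome build is GRCm38.p6, per the submitters' processing notes. The aligner, the counting program, its handling of multi-mapped reads and strand, and the annotation are not given in the sources used here. Genes with near-identical copies or pseudogenes are therefore uncertain in level. Of 54183 lines in the table, 382 carried no gene name and 27 carried a calendar date where a gene name should stand. These lines held between 0.253% and 0.289% of the summed FPKM of a library and were left out. The other 53774 lines had a gene name, and 27873 of them were at 0 in all 6 libraries. A total of 124 names stood on more than 1 line, and these were left out of the gene lists. All columns of samples in the table were used.

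FPKM hides depth, so the low values were multiplied by the exon length of each gene in the GENCODE annotation of the same build (release M21). In each library most products were whole multiples of 1 step, and the step gives the number of reads (or fragments) by which the authors divided. That number was 18553401, 19464839 and 25544666 in the oil libraries and 22028209, 18120332 and 23478589 in the libraries labelled tamoxifen. Between 95.0% and 95.3% of the values of up to 1000 reads came out whole within 0.02 reads. Of the named lines, 51889 (96.5%) matched 1 annotated gene, and 50639 of these were whole in all 6 libraries, a number that includes genes at 0 throughout. Of the 10781 matched genes with a mean of at least 1 FPKM, 93.2% were whole in all 6. Gene coordinates come from that annotation.

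The comparison of tamoxifen with oil used limma-trend on log2(FPKM + 1), without a further scaling and without covariates. Fold changes are on that scale, which understates the change of low genes. Genes entered with a mean of at least 1 FPKM over the 6 libraries, which left 10920 genes. The p-values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. Manf also had an exact permutation test. For each gene list the counts of passing members are given both over all genes tested and adjusted over the list alone. Lists with at least 5 measured members were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes. Of 30 lists fixed in advance 25 had enough members, and the adjustment ran over these 25. Camera was repeated with an estimated correlation and on ranks, and the rotation test fry was run beside it.

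The groups, the tests, the lists and the rule for the genes named were set before the data were examined. The rule takes Manf, the sort and Cre driver genes Ptprc, Adgre1 and Cx3cr1, and the 8 highest and 8 lowest protein-coding genes past the threshold. Where fewer than 8 pass, it fills up with the smallest p, given as values only. From each list it takes the 4 members with the smallest p, and 2 from lists of other cell types or of RNA quality. Genes named outside this rule are marked as such, and 1 gene that the rule takes is not reported here.

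Alternatives set in advance were other pseudocounts, no filter and a filter at 5 FPKM, 3 other scalings of the libraries, limma without the trend or with a robust prior, the replicate number as a block, and each library left out in turn. Library quality weights and limma-voom on the recovered whole reads were added after seeing the data. The fit was tested on simulated data with 9925 genes of known change and the spread of both groups. It recovered 27.0% of genes changed 1.5-fold, 73.85% of those changed 2-fold and all 60 of those changed 4-fold, and it called 3 of 9737 unchanged genes. The simulated genes were drawn independently and with the same spread in both groups. In the real libraries genes vary together and tamoxifen 1 stands apart, so these shares may overstate the recovery there. Of 100 unchanged lists of simulated independent genes, 3 had a camera p under 0.05. R 4.3.3 with limma 3.58.1 and Python 3.11 with pandas and NumPy were used.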

Results

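The data set holds gene expression of macrophages taken from injured mouse muscle at day 3, with 3 libraries from oil-treated mice and 3 from mice given tamoxifen to delete Manf. Manf encodes mesencephalic astrocyte-derived neurotrophic factor, a secreted protein of the endoplasmic reticulum (ER) that is induced by ER stress. The design asks which transcripts differ when Cx3cr1-expressing macrophages lack it. Depth, as recovered from the values, lay between 18120332 and 25544666 reads per library.

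The deleted gene did not separate the groups. Manf (chromosome 9, 106838312 to 106891979, minus strand, GRCm38) was at 29.5, 33.0 and 31.4 FPKM in the oil libraries. It was at 18.1 FPKM in the library labelled tamoxifen 1, below every oil library, but at 42.5 and 38.0 FPKM in the libraries labelled tamoxifen 2 and 3, above every oil library. The log2 fold change was -0.02 (SE 0.29, n = 3 per group, limma-trend adjusted p = 0.976), and the exact two-sided permutation p was 1, where the smallest the design allows is 0.1. Without the library labelled tamoxifen 1 the fold change was 0.35 (limma-trend adjusted p = 0.0214), opposite to a deletion, and without oil 2 it was 0.02. An FPKM of the whole gene also counts exons outside the deleted part, and the deleted exon is not given in the sources used here, so these levels do not show whether the protein was lost. The libraries are therefore called by their labels, and every direction below is that of the libraries labelled tamoxifen against oil.

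Of the genes used for sorting, Adgre1 (F4/80) was at 353 ± 27.8 FPKM in oil and 329 ± 35.1 FPKM in the libraries labelled tamoxifen (SD, n = 3). Ptprc (CD45) was at 50.7 ± 3.60 and 39.0 ± 6.88 FPKM. Cx3cr1, the gene whose promoter drives the recombinase, was at 51.7, 42.7 and 51.0 FPKM in oil and at 31.3, 9.82 and 24.6 FPKM in the libraries labelled tamoxifen 1, 2 and 3. Among the 11 measured members of the list of general macrophage and sort genes, 5 fell and 1 rose when adjusted over the list alone, and 0 passed over all genes. Csf1r, the receptor for macrophage colony-stimulating factor, fell from 410 ± 31.7 to 286 ± 34.8 FPKM, and Lyz2 (lysozyme) fell from 9343 ± 824 to 7071 ± 314 FPKM, while Fcgr1 rose from 129 ± 11.6 to 157 ± 7.08 FPKM. These counts were 0 without any 1 of oil 1, oil 2, oil 3 or tamoxifen 3 and without a filter. They were 1 lower and 0 higher with median-of-ratios scaling, 3 and 0 with quantile normalization, and 2 and 0 without the trend. Camera placed the list lower than other genes (adjusted p = 0.0433, and adjusted p = 0.58 with an estimated correlation), a call lost without oil 1, oil 3 or tamoxifen 3, without a filter (adjusted p = 0.106) and on ranks (adjusted p = 0.0537).

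**Figure D1:**
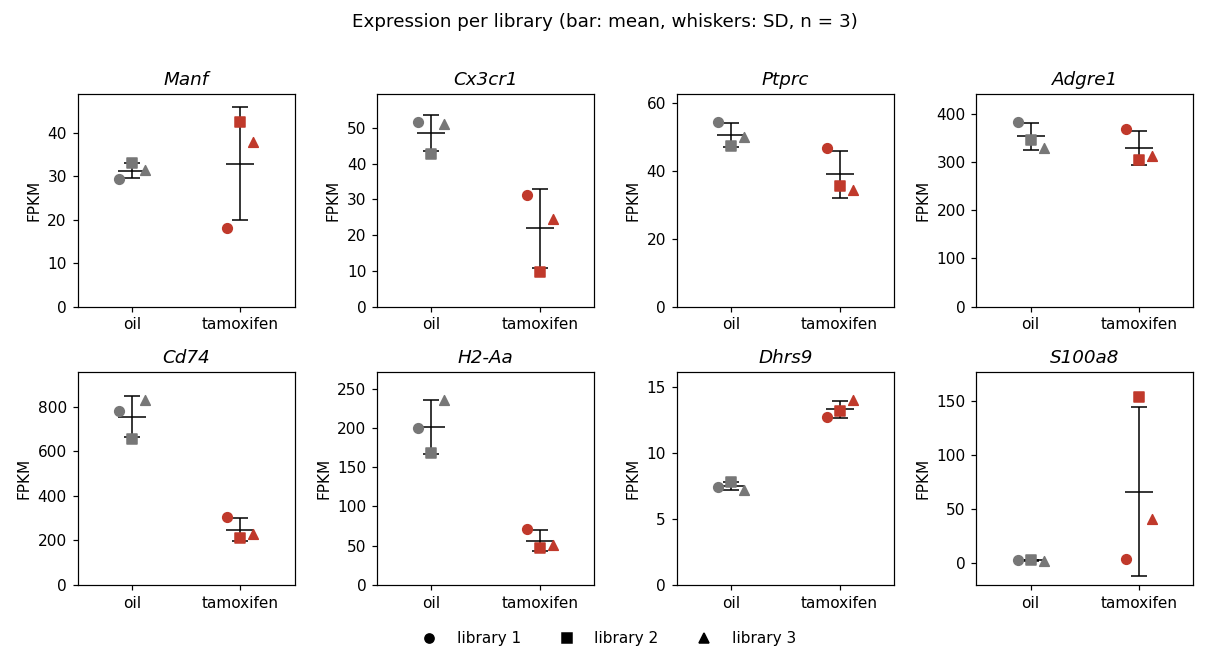
FPKM of 8 genes in each library, with oil in grey and libraries labelled tamoxifen in red, marker shape giving the library number, horizontal bars the mean and whiskers the SD (n = 3). Manf lies at 18.1, 42.5 and 38.0 FPKM in the libraries labelled tamoxifen 1, 2 and 3, while Cd74 and H2-Aa lie below and Dhrs9 above every oil library in all 3.

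Across 10920 genes, limma-trend called 0 genes higher and 0 lower with tamoxifen, and the smallest adjusted p was 0.0805. At an unadjusted p under 0.05 there were 2723 genes, 1440 higher and 1283 lower, where chance gives 546. The larger side depended on the scaling: there were 1318 higher and 1419 lower with median-of-ratios scaling, 1224 and 1361 with each library rescaled to the same sum, and 1351 and 1341 with quantile normalization. All 3 libraries labelled tamoxifen lay above all 3 oil libraries in 1764 genes and below them in 1505, together 29.9% of genes, where chance gives 10%. The library labelled tamoxifen 1 stood nearer to oil than the other two on the first principal component (67.7% of the variance), which placed the oil libraries at -22.5, -13.5 and -13.5 and the libraries labelled tamoxifen at -6.80, 34.3 and 22.1. The second (10.4%) set tamoxifen 1 apart, at -17.2 against 0.418 to 8.88 in the other libraries. Its chi-square per degree of freedom, from recovered reads, against each oil library was 15.2 or more, where pairs of oil libraries reached at most 11.25. Without tamoxifen 1, limma-trend called 1901 genes higher and 1583 lower, and without any other single library it called 0. Limma-voom on the recovered reads called 1 gene higher and 3 lower. Of the 25 gene lists tested, camera called 5 higher and 7 lower. None held with an estimated correlation or with fry, and 5 of the 10 ways to split the 6 libraries 3 against 3, the real one included, called at least 12 lists.

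The genes with the smallest p, none of which passed over all genes, were transcripts of antigen presentation on the lower side. Cd74, the invariant chain (chromosome 18, 60803848 to 60812652), was at 756 ± 90.8 FPKM in oil and 248 ± 51.3 FPKM with tamoxifen, a log2 fold change of -1.62 (SE 0.17, limma-trend adjusted p = 0.0805). H2-Aa, H2-Ab1 and H2-Eb1, chains of the class II molecules on chromosome 17, had log2 fold changes of -1.83, -1.71 and -1.63 with the same adjusted p of 0.0805. Gpx7, F11r, Hpgd and Pxdc1 followed, with log2 fold changes of -0.74, -0.66, -1.96 and -2.13 and limma-trend adjusted p of 0.147. On the higher side stood Dhrs9, a retinol dehydrogenase (chromosome 2, 69380445 to 69404533), at 7.47 ± 0.309 FPKM in oil and 13.3 ± 0.658 FPKM with tamoxifen, a log2 fold change of 0.75 (SE 0.07, limma-trend adjusted p = 0.0805). Spp1 (osteopontin), among the most abundant transcripts, was at 4715 ± 289 and 8743 ± 739 FPKM, and Csf1, the macrophage growth factor, at 3.71 ± 0.796 and 8.005 ± 0.867 FPKM. Slfn4, a Schlafen family gene with close relatives, was at 18.9 ± 6.72 and 88.5 ± 12.8 FPKM. Cd300e, Flrt2, Ccl12 and Ass1 had log2 fold changes of 0.94, 0.76, 1.61 and 0.91. With the filter set at 5 FPKM, Dhrs9 rose and Cd74, H2-Aa, H2-Ab1 and H2-Eb1 fell, the smallest adjusted p being 0.0441.

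Transcripts of MHC class II antigen presentation were lower in all 3 libraries labelled tamoxifen, and 8 of the 12 measured members fell when adjusted over the list alone. The lowest of these adjusted p, shared by Cd74, H2-Aa, H2-Ab1 and H2-Eb1, was 0.00011. The median member lay 0.50, 1.03 and 0.95 log2 units below the oil mean in the libraries labelled tamoxifen 1, 2 and 3. Ciita, the transactivator of class II genes, named here after its values were seen, was at 2.68, 1.91 and 2.07 FPKM in oil and at 0.895, 0.203 and 0.277 FPKM with tamoxifen (log2 fold change -1.17). Leaving out 1 library gave between 7 and 11 lower members, and limma-voom, with 8 members measured, gave 4. Camera placed the list lower than other genes (adjusted p = 4.2e-08, and adjusted p = 0.58 with an estimated correlation).

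In the dendritic cell list, 1 of 6 measured members, Cd209a, fell when adjusted over the list alone, from 4.50 ± 1.46 to 1.33 ± 0.724 FPKM, and Irf8 was at 23.9 ± 1.05 and 16.7 ± 6.99 FPKM. Camera placed this list lower (adjusted p = 0.0152, and adjusted p = 0.58 with an estimated correlation), a call lost without oil 3, and Cd209a did not pass without tamoxifen 3. Too few members were measured for a list test of T and NK cell markers or of B cell markers. Among the 3 measured T and NK cell markers, Cd4 fell from 4.22 ± 0.986 to 0.769 ± 0.748 FPKM when adjusted over the list alone, and Cd2 was at 1.66 ± 0.177 and 2.04 ± 0.867 FPKM. Among the 3 measured B cell markers 2 fell and 1 rose when adjusted over the list alone: Ighm fell from 27.0 ± 2.86 to 9.96 ± 7.79 FPKM and Cd79b from 4.17 ± 0.433 to 2.94 ± 0.846 FPKM. None of the B cell markers passed without any 1 library other than tamoxifen 1.

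Transcripts of Ly6C-high, recently recruited monocytes were higher in all 3 libraries labelled tamoxifen. Of 23 measured members 17 rose and 3 fell when adjusted over the list alone, and 0 passed over all genes. Cd177 rose from 3.91 ± 1.43 to 9.35 ± 1.10 FPKM, Fcnb (ficolin B) from 0.247 ± 0.0928 to 2.09 ± 1.12 FPKM and Ifitm6 from 7.22 ± 3.03 to 29.5 ± 12.5 FPKM. Ly6c2, named after its values were seen and close in sequence to Ly6c1, was at 21.4, 51.8 and 46.9 FPKM in oil and at 152, 123 and 83.8 FPKM with tamoxifen. The 3 members that fell, named after their values were seen, were Lyz2, Mgst1 and Itgal. Ace and Nr4a1, also named after their values were seen, had log2 fold changes of -0.19 and -0.32 and did not pass. Leaving out 1 library gave between 11 and 17 higher members. Camera placed the list higher (adjusted p = 0.00012, and adjusted p = 0.58 with an estimated correlation).

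Of the 9 measured neutrophil markers 0 passed, and camera did not call the list (adjusted p = 0.333), with 5 higher and 1 lower without tamoxifen 1. S100a8, an abundant neutrophil protein, was at 2.64, 3.04 and 1.52 FPKM in oil and at 4.12, 154 and 40.4 FPKM in the libraries labelled tamoxifen 1, 2 and 3, and Lcn2 was at 0.363, 33.6 and 8.59 FPKM there, with 6 of the 9 fold changes above 0. Of the remaining members, named after their values were seen, S100a9, Mmp8, Il1r2 and Retnlg had log2 fold changes of 3.11, 0.74, 0.53 and 0.03, and Mmp9, Mpo and Csf3r had -0.01, -0.20 and -0.54. Ear2, the only measured eosinophil marker, was at 6.55 ± 1.85 FPKM in oil and 14.0 ± 6.57 FPKM with tamoxifen, with overlapping libraries. It did not pass over all genes (limma-trend adjusted p = 0.172). As a list of 1 member its p is unadjusted (0.0312), and it lay above 0.05 without oil 1, oil 2, tamoxifen 2 or tamoxifen 3. In the list of inflammatory cytokines and mediators 0 of 26 members passed, and camera did not call it (adjusted p = 0.114). Camera did call it higher without a filter (adjusted p = 0.0338) and without oil 3, tamoxifen 1 or tamoxifen 3 (adjusted p between 0.0219 and 0.0379), and without tamoxifen 1 there were 9 higher members and 1 lower. Ccl7 and Ccl2, chemokines that attract monocytes, were at 187 ± 40.8 and 165 ± 27.5 FPKM in oil and at 551 ± 212 and 458 ± 200 FPKM with tamoxifen, Tnf at 127 ± 10.5 and 180 ± 45.7 FPKM, and Ptgs2 at 34.1 ± 2.76 and 62.1 ± 32.2 FPKM.

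All 32 measured members of the list of ER chaperones and ER-associated degradation, which fold and clear proteins in the ER, had a fold change above 0. None passed either over all genes or adjusted over the list alone, but the list as a whole was higher by camera (adjusted p = 4.2e-08, and adjusted p = 0.61 with an estimated correlation). The median member lay 0.08, 0.50 and 0.43 log2 units above the oil mean in the libraries labelled tamoxifen 1, 2 and 3, so that tamoxifen 1 contributed little. Sec61b was at 57.3 ± 2.90 and 82.9 ± 12.2 FPKM, Pdia6 at 133 ± 5.64 and 212 ± 45.7 FPKM, Ostc at 28.7 ± 0.511 and 41.6 ± 7.15 FPKM and Selenos at 38.4 ± 1.81 and 53.9 ± 9.80 FPKM. Without tamoxifen 1, 28 of the members rose when adjusted over the list alone, and without any other library 0 did.

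Targets of PERK and ATF4, the arm of the ER stress response that slows translation, were higher by camera (adjusted p = 0.0113, and adjusted p = 0.61 with an estimated correlation), a call that was lost without tamoxifen 2 (adjusted p = 0.0941). Of 26 measured members 2 rose and 1 fell when adjusted over the list alone: Nupr1 rose from 5.99 ± 0.406 to 11.9 ± 2.49 FPKM, Slc7a5 from 7.72 ± 1.14 to 15.1 ± 4.06 FPKM, and Pck2 fell from 4.30 ± 0.351 to 2.12 ± 0.728 FPKM. Sesn2 was at 10.9 ± 0.367 and 13.6 ± 1.32 FPKM. Without oil 1, oil 2, oil 3 or tamoxifen 3 no member passed, and without tamoxifen 1 there were 14 higher and 3 lower.

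Genes of cholesterol synthesis and uptake and of glycolysis were higher by camera, with 0 members passing in either list. Without tamoxifen 1, 17 of 22 cholesterol genes rose when adjusted over the list alone, and 9 of 19 glycolysis genes rose and 2 fell. For cholesterol genes the adjusted p was 0.00051, and the adjusted p was 0.77 with an estimated correlation. Sqle was at 4.55, 11.9 and 9.18 FPKM in the libraries labelled tamoxifen 1, 2 and 3 against 3.94 ± 0.811 FPKM in oil, Idi1 at 3.13 ± 0.724 and 7.23 ± 3.61 FPKM, Hsd17b7 at 1.01 ± 0.245 and 2.26 ± 1.01 FPKM, and Srebf2, a regulator of this pathway, at 15.6 ± 2.22 and 26.6 ± 8.86 FPKM. For glycolysis the adjusted p was 0.0084, and the adjusted p was 0.58 with an estimated correlation. Pkm was at 289 ± 23.9 and 416 ± 73.3 FPKM, Eno1 at 117 ± 8.80 and 168 ± 30.6 FPKM, Pfkp at 7.71 ± 0.689 and 10.6 ± 1.66 FPKM, and Pfkm, lower, at 3.03 ± 0.413 and 1.93 ± 0.514 FPKM. Gapdh, named after its values were seen and with many pseudogenes, ran from 2.65 to 22.8 FPKM between oil libraries and is uncertain.

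**Figure D2:**
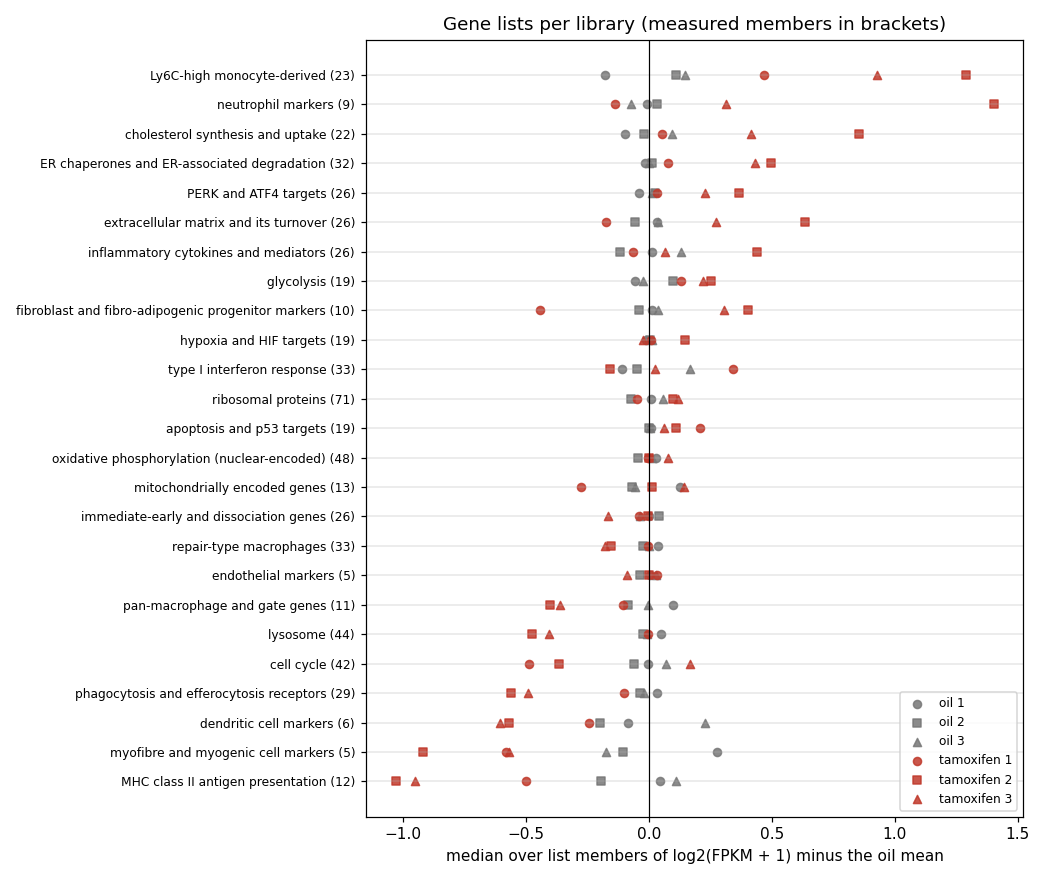
Median over the measured members of each tested gene list of log2(FPKM + 1) minus the oil mean (horizontal axis), with 1 point per library, oil in grey and libraries labelled tamoxifen in red, marker shape giving the library number. For MHC class II genes tamoxifen 1, 2 and 3 lie at -0.50, -1.03 and -0.95, while for ER chaperones they lie at 0.08, 0.50 and 0.43.

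The list for phagocytosis and the uptake of dead cells, which holds receptors, their ligands and other genes, was lower by camera (adjusted p = 3.8e-05, and adjusted p = 0.58 with an estimated correlation). Of 29 measured members 13 fell and 2 rose when adjusted over the list alone. The 2 that rose were the receptors Msr1 and Fcgr1 (log2 fold changes 0.72 and 0.28). Those that fell included the receptors or receptor subunits Mertk, Stab1, Itgb5 and Fcgr2b (-0.66, -0.35, -0.64 and -0.64). Of these, all but Fcgr1 are named after their values were seen. Gas6, a bridge between dying cells and the receptor Mertk, fell from 121 ± 5.85 to 80.7 ± 11.7 FPKM, the complement gene C1qa from 1461 ± 127 to 796 ± 270 FPKM, Ucp2 from 151 ± 7.41 to 121 ± 4.13 FPKM and Pros1 from 24.4 ± 1.44 to 19.6 ± 1.06 FPKM. Without any 1 library other than tamoxifen 1 these counts were 0, and without tamoxifen 1 they were 22 lower and 4 higher. Lysosomal genes were lower by camera (adjusted p = 6.8e-06, and adjusted p = 0.66 with an estimated correlation), with the median member at 0.00, -0.48 and -0.41 log2 units from the oil mean in tamoxifen 1, 2 and 3. Of 44 measured lysosomal members 1 fell and 1 rose when adjusted over the list alone, none passed without oil 1, oil 3, tamoxifen 2 or tamoxifen 3, and without tamoxifen 1 there were 32 lower and 3 higher. Ctsf fell from 3.69 ± 1.19 to 0.917 ± 0.381 FPKM, Ctsl rose from 285 ± 9.62 to 405 ± 38.7 FPKM, Scarb2 was at 52.4 ± 3.03 and 35.6 ± 8.4997 FPKM, and Acp5 was at 91.9 ± 20.6 and 48.6 ± 18.6 FPKM. Genes of repair-type macrophages were not called as a list (adjusted p = 0.394): of 33 members 1 rose when adjusted over the list alone, namely Spp1, with 0 when any 1 oil library was left out and 9 higher and 15 lower without tamoxifen 1. Selenop was at 801 ± 144 and 301 ± 206 FPKM, Tgfb1 at 111 ± 4.62 and 85.4 ± 8.90 FPKM, and Anxa1 at 181 ± 11.2 and 292 ± 66.4 FPKM.

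Cell cycle genes were lower by camera (adjusted p = 0.0113, and adjusted p = 0.83 with an estimated correlation), a call that was lost without tamoxifen 1 (adjusted p = 0.835) and with library weights (adjusted p = 0.284), where the direction was upward and 14 members were higher and 1 lower. The median member was at -0.49, -0.37 and 0.17 log2 units from the oil mean in tamoxifen 1, 2 and 3, and 0 of 42 members passed. In the reported fit 28 members had a fold change below 0 and 14 above 0, so the fall did not hold across the list. Those above 0, named after their values were seen, were Ccne1, Ccne2, Cdc6, Cdc45, Cdt1, Mcm2 to Mcm7, Pcna, E2f1 and Gins2. Without tamoxifen 3 there were 22 lower members when adjusted over the list alone, and without tamoxifen 1 there were 8 higher and 1 lower. Ccnb2 was at 39.2 ± 0.924 and 27.1 ± 3.85 FPKM, Nusap1 at 7.83 ± 0.893 and 4.74 ± 1.52 FPKM, Tk1 at 9.41 ± 1.08 and 6.54 ± 1.20 FPKM, and Cenpf at 1.36 ± 0.109 and 0.831 ± 0.155 FPKM. Transcripts of muscle fibres and myogenic cells, low in these sorted cells, were lower by camera (adjusted p = 0.0037, and adjusted p = 0.58 with an estimated correlation), and 3 of the 5 measured members fell when adjusted over the list alone. Myog fell from 2.51 ± 0.905 to 0.587 ± 0.444 FPKM and Mylpf from 1.82 ± 0.494 to 0.675 ± 0.238 FPKM.

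Camera did not call the other lists. Among 19 measured apoptosis and p53 genes 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.231), and Cdkn1a rose from 179 ± 10.5 to 226 ± 16.9 FPKM, Bcl2l1 from 16.5 ± 2.03 to 22.8 ± 0.734 FPKM and Aen from 2.67 ± 0.242 to 3.84 ± 0.360 FPKM, while Sesn1 fell from 12.1 ± 2.40 to 7.05 ± 1.42 FPKM. Without oil 1, oil 2, tamoxifen 2 or tamoxifen 3 no member passed, and without a filter camera called the list higher (adjusted p = 0.0242). Among 33 interferon response genes 2 rose when adjusted over the list alone (camera adjusted p = 0.317): Oasl1 from 16.4 ± 2.12 to 26.5 ± 2.75 FPKM and Oas1a, which has close relatives, from 63.9 ± 4.84 to 88.5 ± 5.85 FPKM. Without oil 1, oil 2 or tamoxifen 3, or with quantile normalization, neither passed, and without oil 3 or tamoxifen 2 camera called the list higher (adjusted p = 0.0202 and 0.0047), with 5 higher members without oil 3. Without tamoxifen 1 there were 2 higher and 4 lower members, and with library weights 4 higher and 3 lower. Camera's direction was downward in both, with no call (adjusted p = 0.335 and 0.911). Gbp3 was at 15.9 ± 2.15 and 8.95 ± 2.89 FPKM and Ifi27l2a at 367 ± 65.9 and 550 ± 76.8 FPKM. Matrix genes (camera adjusted p = 0.273) had 1 member of 26 that rose, Spp1, which did not pass without oil 3, and without tamoxifen 1 there were 15 higher and 3 lower (camera adjusted p = 0.0159), with Adam8 at 194 ± 19.1 and 288 ± 57.7 FPKM, Plau at 246 ± 15.8 and 365 ± 74.2 FPKM and Timp2 at 189 ± 7.67 and 128 ± 32.3 FPKM.

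No member passed in the lists of hypoxia targets (camera adjusted p = 0.905), nuclear-encoded oxidative phosphorylation genes (adjusted p = 0.394), ribosomal proteins (adjusted p = 0.128), fibroblast and progenitor markers (adjusted p = 0.645), endothelial markers (adjusted p = 0.606), immediate-early and dissociation genes (adjusted p = 0.273) and mitochondrially encoded genes (adjusted p = 0.729). Ribosomal proteins were called higher without a filter and without oil 3 or tamoxifen 1 (adjusted p between 0.0049 and 0.028), and with library weights (adjusted p = 0.0014). Without tamoxifen 1, members passed in each of these lists except the mitochondrially encoded genes, at most 6 higher (hypoxia targets) and 7 lower (immediate-early and dissociation genes). Examples were Selenbp1 at 8.13 ± 0.750 and 5.59 ± 0.831 FPKM, Ero1l at 8.73 ± 0.310 and 13.7 ± 3.47 FPKM, Cycs (cytochrome c) at 19.2 ± 1.82 and 31.0 ± 5.99 FPKM and Ndufa1, of the same list and lower, at 93.4 ± 9.98 and 75.8 ± 10.5 FPKM. Of the fibroblast and progenitor markers, Serpinf1 was at 3.82 ± 0.432 and 2.61 ± 0.514 FPKM and Gsn at 170 ± 10.7 and 215 ± 26.2 FPKM. Of the immediate-early genes, Fosb was at 259 ± 17.2 and 202 ± 32.6 FPKM and Egr1 at 60.4 ± 3.60 and 47.5 ± 7.84 FPKM. Hbb-bs, the only measured erythroid marker, was at 1.24 ± 0.587 and 1.70 ± 0.960 FPKM, and none of the mast cell and basophil markers reached the filter.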

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

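The library weights and limma-voom were chosen after seeing the data; the other alternatives were set in advance. Of 10920 genes 0 higher and 0 lower passed as reported. Without a filter 1 gene was lower, and 8 lists were higher by camera. A filter at 5 FPKM called 1 gene higher and 4 lower. Library quality weights called 2704 higher and 2037 lower, with tamoxifen 1 at a weight of 0.199 and tamoxifen 3 at 3.77, and limma-voom called 1 higher and 3 lower. Leaving out 1 library gave between 0 and 1901 genes higher and between 0 and 1583 lower, all from leaving out tamoxifen 1. It gave between 5 and 8 lists higher and between 5 and 7 lower. With an estimated correlation, and with fry, camera's 5 higher and 7 lower lists became 0 and 0. The log2 fold change of Manf ran from -0.24 to 0.35 over the libraries left out, and it was 0.23 with library weights; it crossed 0 without oil 2 (0.02) and without tamoxifen 1. Of the named genes, Hbb-bs ran from -0.029 (without tamoxifen 2) to 0.42 over the libraries left out, and mt-Nd3 turned to 0.15 with library weights. Except where fewer samples or genes entered, the cause was not tested.

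Replicate numbers as a block gave 11 genes higher and 22 lower. Same-number deviations correlated at 0.261, 0.088 and 0.004 across genes, and not every library matched its own number best, so the numbers are not read as pairs.

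Other pseudocounts, scalings and prior settings left the count over all genes at 0, while counts adjusted over a list alone moved in some lists.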

Other observations

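Some gene lists and genes also differed between the libraries labelled tamoxifen. The median interferon response gene lay at 0.34 log2 units from the oil mean in tamoxifen 1, at -0.16 in tamoxifen 2 and at 0.02 in tamoxifen 3. Fibroblast and progenitor markers had medians of -0.45, 0.40 and 0.30. Lyve1, a gene of tissue-resident macrophages, named after its values were seen, was at 4.45, 47.0 and 24.7 FPKM in these libraries and at 2.99, 3.26 and 4.41 FPKM in oil (log2 fold change 2.06, SE 0.73, limma-trend adjusted p = 0.164).

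All tests in this part were chosen after the values were seen. The first pattern is that tamoxifen 1 lay nearer the oil libraries than the other two did, with correlations across genes of 0.984 to 0.990 with oil, against 0.948 to 0.975 for tamoxifen 2 and 3. The highest correlation of tamoxifen 1 with an oil library (0.9904) was above the lowest among oil libraries (0.9896). If tamoxifen 2 and 3 show the treated state, an exchange of labels would leave an oil library nearer to them than to another oil library, and 0 were. If they stand apart for another reason, this test cannot decide about an exchange. In Manf, tamoxifen 1 was unlike a further oil-treated mouse, at -0.755 log2 units from the oil mean. That is outside the 95% prediction interval for 1 more oil library (0.40 either way). One mixing share of cells like those of tamoxifen 2 would give the same share from each list. The share from MHC class II genes (0.63) exceeded that from lysosomal genes (0.13) by 0.504 (SE 0.13). The SE of a share comes from leaving out single genes of the list in turn. It treats the genes of a list, which vary together, as independent and holds no spread between libraries. The difference therefore does not decide against mixing. The difference also rests on the class II genes: the shares from ER chaperones and Ly6C-high genes were 0.08 (SE 0.04) and 0.16 (SE 0.07) against tamoxifen 2. Against tamoxifen 3 they were 0.07 (SE 0.04) and 0.36 (SE 0.13), where lysosomal genes gave 0.17 (SE 0.11). The largest difference among these 3 lists was 2.06 of these standard errors. Mixing stays open, as does the untested extent of deletion in each mouse.

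The second pattern is that Manf was above every oil library in tamoxifen 2 and 3. One candidate explanation is that Manf rose with the ER chaperones and hid a loss, and it stays open: Manf exceeded 43.75% of the chaperone list in tamoxifen 2 and 21.9% in tamoxifen 3, and none of it in tamoxifen 1. Another is fewer Cx3cr1-expressing cells in these libraries. In 3 of the 3 pairs of libraries labelled tamoxifen more Manf went with less Cx3cr1, but 3 libraries are too few to decide. Less deletion for that reason would at most return Manf to the oil level (29.5 to 33.0 FPKM). It would not by itself give the 42.5 and 38.0 FPKM of tamoxifen 2 and 3. Counting of a shortened transcript was not tested.

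The third pattern is that MHC class II genes were lower in all 3 libraries labelled tamoxifen. The authors' scaling is argued against, since the median fold change of the list stayed at -0.849 or lower under 3 other scalings. Fewer dendritic cells may account for part of it, and how many of them the F4/80 gate removed was not measured. Their markers had a median log2 fold change of -0.532 (SD 0.44 over 6 markers) against -1.62 for Cd74. However, 4 of 6 lay under 3 FPKM in oil, so fewer dendritic cells cannot be told apart from a change within macrophages. Tamoxifen itself and any loss of Manf cannot be told apart by treatment group, because no tamoxifen-treated mice of another genotype were analysed here. Manf transcript was low only in tamoxifen 1 (18.1 FPKM, against 42.5 and 38.0 FPKM in tamoxifen 2 and 3). The median class II member lay at -0.50, -1.03 and -0.95 log2 units in tamoxifen 1, 2 and 3, so the fall was not largest where Manf was lowest. A change of cell state with the treatment is a hypothesis that remains open.

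The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes called, all 10 splits gave 0. For genes at an unadjusted p under 0.05, 1 split, the real one, reached 2723, and the highest other split gave 1553. For lists called by camera, 5 splits gave at least the real 12, and the highest other gave 15. Splits that put oil 3, oil 2 or oil 1 beside tamoxifen 2 and 3 gave 13, 12 and 15 lists. These splits keep the difference of tamoxifen 2 and 3 from the other oil libraries, so their counts do not show what chance would give. The split of oil 1, oil 3 and tamoxifen 3 against the rest also gave 12 lists, with tamoxifen 2 and 3 on opposite sides. The count of lists therefore does not set the real split apart.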
